A study of Mus musculus with 2 samples.

How the data were processed

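One pool of sorted heart cells from operated mice was measured as 1 transcriptome library and 1 hashtag library, the 2 GEO samples of the series, made on the BD Rhapsody platform with the TAS-Seq workflow. Per the submitters' processing notes, cutadapt 4.1, STARsolo 2.7.10b with STAR, R 4.3.1 and the mouse genome build GRCm39 were used, with no role or order stated. The transcriptome file, as deposited by the authors, holds estimated counts per gene and cell that are not normalized: 69.8% of the values above 0 are whole numbers and the rest are fractions. The hashtag file, as deposited by the authors, holds whole counts per tag for 1000000 barcodes. Whether either file counts molecules or reads is not given in the sources used here. Among 10657 genes found in 1% to 5% of cells, 58.0% of the values above 0 equal 1 and 7.41% are 10 or more. Counts may therefore not be independent molecules, which makes the counting intervals too narrow if they are reads. Each cell name in the transcriptome file starts with the authors' tag call, A951, A952, A953, A965 or doublet, and these calls were used as given. No source used here ties a tag to a sorted fraction, so the comparisons of GFP-positive with GFP-negative cells and the class shares by fraction, which had been planned, were not run. Values by tag name describe the cells so named and do not compare sorted fractions.

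Cells were kept with at least 500 counts, at least 200 genes and at most 25% mitochondrial counts. This left out 21 of 878 cells, 15 named A951 and 6 named doublet, and none for low counts or genes. Cells named doublet that passed stayed in the classes, since no fractions were compared. Counts were scaled to 10000 per cell and log1p-transformed, and 2000 variable genes were taken after genes of the fixed gene lists that are not cell type markers had been left out. Principal components (30), a graph of 15 neighbours and Leiden clustering at resolution 1 with seed 0 gave 10 clusters. A cluster was named after a marker list when at least 3 of its markers reached a counts-per-million value (CPM) of 50 and 2 times the level of all other cells. Ties were broken by the 10 leading genes of the cluster, a rule chosen after seeing the data, and clusters with no match stayed unnamed. Leading genes were ranked by the ratio to all other cells with 20 CPM added to both sides. Scrublet marked 2 of the 857 cells (0.233%), neither named doublet.

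Counts of a gene or list were summed over the cells of a class, divided by the class total and scaled to CPM, with exact Poisson intervals for sums and exact Clopper-Pearson intervals for shares and for ratios of summed counts, all at 95%. Where no cell carried a feature, the upper bound of the exact interval is given. Cells with at least 3 markers of a type at 50 CPM or more were also counted among all 878 cells, before any filter. Classes of fewer than 50 cells were left out of the list comparison. In all, 23 gene lists and 23 marker lists with 462 genes were fixed before the data were examined, and 449 of these genes were in the matrix. Members of gene lists that are also cell type markers were left out of the list levels, except in the haemoglobin and cardiomyocyte RNA lists. The median log2 ratio of a list, in a class against all other cells with 1 CPM added, was set against 10000 random lists of the same size drawn from 20 bins of mean expression, over 18243 genes with at least 50 counts. Its percentile describes this library and is not a test across animals, and no p-value is given. The haemoglobin list had fewer than 3 genes with enough counts for this. Genes to be named were fixed by a rule for the case without known fractions: up to 4 members of each list with at least 50 CPM in the class where the list's summed level was highest, ranked by level there, plus Ptprc and any reporter transcript. Ratios of median mitochondrial shares were given with 95% intervals from 10000 bootstrap samples of the cells on each side. For shares of cells with mCherry, counts were thinned to 25000 per cell. Clusters of the same class were compared as an addition chosen after seeing the data, with genes passing at 50 counts over both clusters, 50 CPM in either, an absolute log2 ratio of at least 1 and an interval that excludes a ratio of 1.

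The interval method was tested on simulated data with an arm of 51 cells and 18243 genes, 200 of them changed. Summed counts were drawn from Poisson distributions, without spread between cells or repeated reads. The simulation therefore tests the calculation and not how well the intervals hold for these data. Unchanged genes had a median ratio of 0.994, a true ratio of 2 was returned as 1.99 and a true ratio of 4 as 4.00, and at least 96% of intervals held the true ratio. Of 200 lists of unchanged genes, 15 (7.5%) fell outside the central 95% of random lists, and 50 of 50 lists of genes changed by a ratio of 2 lay above it.

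The alternatives fixed in advance were 1000 counts, at most 10% mitochondrial counts, resolutions 0.5 and 2, 15 components, all variable genes, scrublet doublets left out, tag calls by the highest tag with a share of at least 0.5 or 0.8 or at least 50 tag counts, scaling without mitochondrial, ribosomal and haemoglobin genes, and each cell weighted alike. Alternatives chosen after seeing the data were a tag share of 0.6 with at least 10 counts, cells named doublet left out, tied clusters left unnamed, and each gene without the cell that holds most of its counts. Coordinates are not given, because the build named by the submitters differs from the annotation at hand, which was not used here, and genes are named by the symbols in the matrix. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.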

Results

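Single-cell transcriptomes were collected from the hearts of mice with pressure overload, produced by transverse aortic constriction, an operation that narrows the aorta. The mice carried Cdh5-CreERT2, a tamoxifen-inducible Cre recombinase of endothelial cells, and REFLEX, a reporter system in which, by the series record, GFP marks interacting cells. Cells were sorted by surface CD45, the common leukocyte antigen, and by GFP into CD45-negative GFP-negative, CD45-negative GFP-positive, CD45-positive GFP-negative and CD45-positive GFP-positive cells, which were pooled. The pool gave 1 transcriptome library and 1 hashtag library, so there were no replicates and the cells of the pool are not replicates of each other. Per the labels, 20000 cells were loaded, and the deposited transcriptome matrix held estimated counts of 31192 genes in 878 cells. Estimated counts per cell ranged from 28406.6 to 706332 with a median of 77171, and cells had a median of 3593 genes above 0. After 21 cells with over 25% mitochondrial counts were left out, 857 cells remained. Intervals are exact 95% intervals and cover counting error only.

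The hashtag library, which counts sample tags on each cell, was read for how many cells carried each tag. Cell names in the matrix gave 331 cells to tag A951 (37.7%, 34.5 to 41.0), 134 to A952 (15.3%, 12.9 to 17.8), 114 to A953 (12.98%, 10.8 to 15.4) and 247 to A965 (28.1%, 25.2 to 31.2), and called 52 cells doublets (5.92%, 4.45 to 7.69). The median estimated count per cell was 69203 for cells named A951, 87695 for A952, 81755 for A953, 79106 for A965 and 72084 for doublets. Which tag stands for which fraction was not among the information used here, so tags are given by number and GFP-positive and GFP-negative cells were not compared. The tag counts themselves differed from the names in many cells: the tag in the name had the highest count in 490 of 826 singly named cells (59.3%). It did so in 331 of 331 A951 cells and 128 of 134 A952 cells, but in 14 of 114 A953 cells and 17 of 247 A965 cells. In cells named A953 the median count of their own tag was 6 (quartiles 4 to 13) beside a median of 38.5 A951 counts, and in cells named A965 it was 5 (quartiles 3 to 9) beside 43. A call by the highest tag alone, with at least 0.6 of the tag counts and at least 10 counts, put 72.8% of the 878 cells in A951, 1.37% in A953 and 2.85% in A965.

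**Figure D1:**
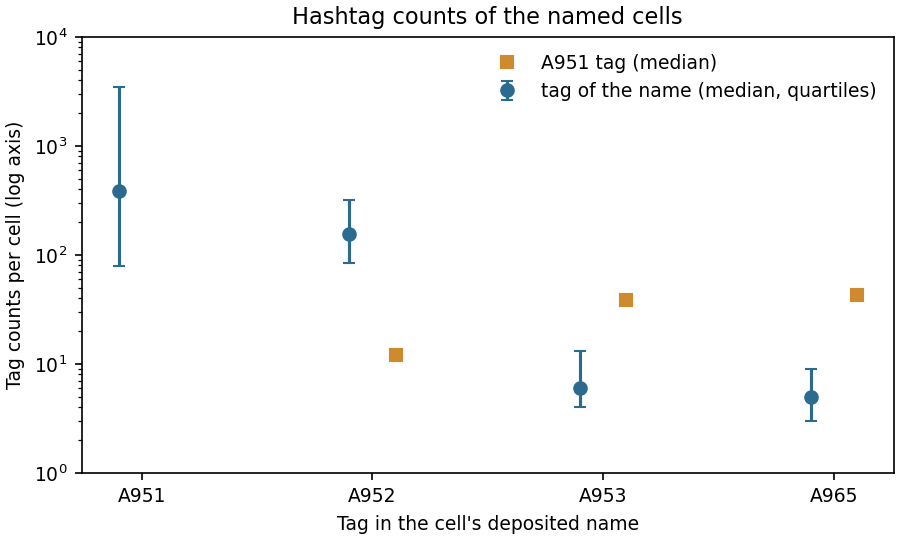
Hashtag counts per cell (log axis) by the tag in the deposited cell name: circles are medians of the named tag with quartiles as bars, and squares are medians of tag A951 in the same cells. Cells named A953 and A965 held medians of 6 and 5 counts of their own tag, below their A951 medians of 38.5 and 43.

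All 7 named classes were leukocytes. Their shares describe the kept cells of this matrix, which came from sorted and pooled fractions. They do not estimate the make-up of leukocytes in the heart. Neutrophil-like cells were the most numerous class with 273 of 857 cells (31.9%, 28.7 to 35.1), followed by monocyte-like cells with 181 (21.1%, 18.4 to 24.0), B cell-like cells with 160 (18.7%, 16.1 to 21.4) and T cell-like cells with 103 (12.02%, 9.92 to 14.4). Macrophage-like cells numbered 51 (5.95%, 4.46 to 7.75), conventional dendritic-like cells 33 (3.85%, 2.67 to 5.37) and NK cell-like cells 27 (3.15%, 2.09 to 4.55). A cluster of 29 cells (3.38%, 2.28 to 4.82) matched no marker list and had a median mitochondrial share of 7.99%. No cell of the 878 had 3 or more markers at a counts-per-million value (CPM) of at least 50 for blood vascular endothelial, endocardial, lymphatic endothelial, pericyte, smooth muscle, glial or epicardial types. For each type, this allows a share of up to 0.419% for cells that meet this marker rule. The same count of 0 was found for plasma cells, mast cells, erythroid cells and platelets. The rule can miss cells of a type: 14 cells met it for conventional dendritic markers, against 33 cells in that class. At least 3 fibroblast markers were found in 4 cells (0.456%, 0.124 to 1.16), 2 of which were over the mitochondrial limit. At least 3 cardiomyocyte markers were found in 11 cells (1.25%, 0.627 to 2.23), 7 of them over that limit. Ptprc was at 0 in 1 of these 4 cells and in 3 of these 11. Plasmacytoid dendritic markers reached this number in 2 cells, innate lymphoid type 2 markers in 15 and dividing-cell markers in 3. The macrophage-like share depended on the grouping: in 5 of the alternative settings no cells stayed unnamed and it lay between 8.34% and 10.0%. Among the monocyte-like cells, 82 formed a cluster with Ace, Treml4 and Nr4a1, markers of the patrolling type. Pecam1, Fabp4 and Flt1 gave this cluster as many endothelial markers, so its name rested on the tie-break. The other endothelial markers reached at most 36.9 CPM in any cluster, and Ptprc stood at 1146 CPM in this cluster. With such ties left unnamed, the monocyte-like share was 11.6%.

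**Figure D2:**
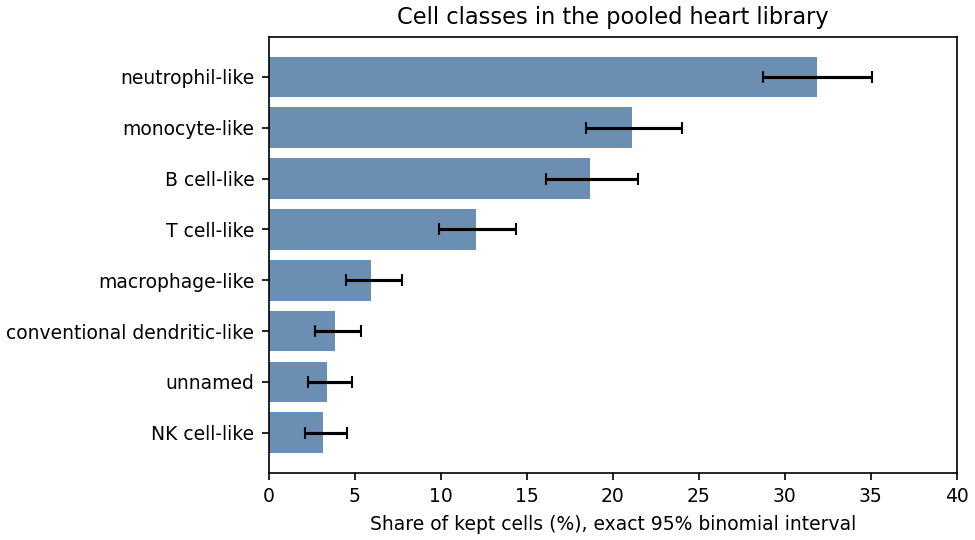
Share of the 857 kept cells in each marker-named class (horizontal axis, percent), with exact 95% binomial intervals as bars. Neutrophil-like cells led with 31.9%, and the 3 smallest groups each held under 4% of cells.

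Transcripts of the sorted antigen and of the reporter were read next, as a check of the sort. Ptprc, which encodes CD45, was present in every class: summed over the cells of a class and scaled to CPM, the unit for expression levels throughout, it was highest in NK cell-like cells at 1489.6 (1436 to 1545) and neutrophil-like cells at 1088 (1073 to 1103), and lowest in macrophage-like cells at 263 (255 to 272). The only reporter transcript found in the matrix by name was mCherry, a red fluorescent protein, whose role in the reporter is not given in the sources used here. It reached 705 CPM (693 to 717) in neutrophil-like cells, 487 (479 to 495) in monocyte-like cells, 382 (369 to 394) in conventional dendritic-like cells and 365 (355 to 375) in macrophage-like cells. Lymphocytes held less, with 274 (251 to 298) in NK cell-like, 190.3 (182 to 199) in T cell-like and 186 (178 to 194) in B cell-like cells. At an equal depth of 25000 counts per cell, mCherry was found in 91.6% of neutrophil-like cells (87.6 to 94.6), 93.9% of monocyte-like cells (89.4 to 96.9) and 49.4% of B cell-like cells (41.4 to 57.4). The pool held no cells known to lack the transgene, so the share that free RNA gives is unknown. By tag, Ptprc ranged from 649.8 CPM in A952 to 747 in A953, and mCherry from 355 in A953 to 435 in A952. Cells named doublets had 944 for Ptprc and 648 for mCherry.

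**Figure D3:**
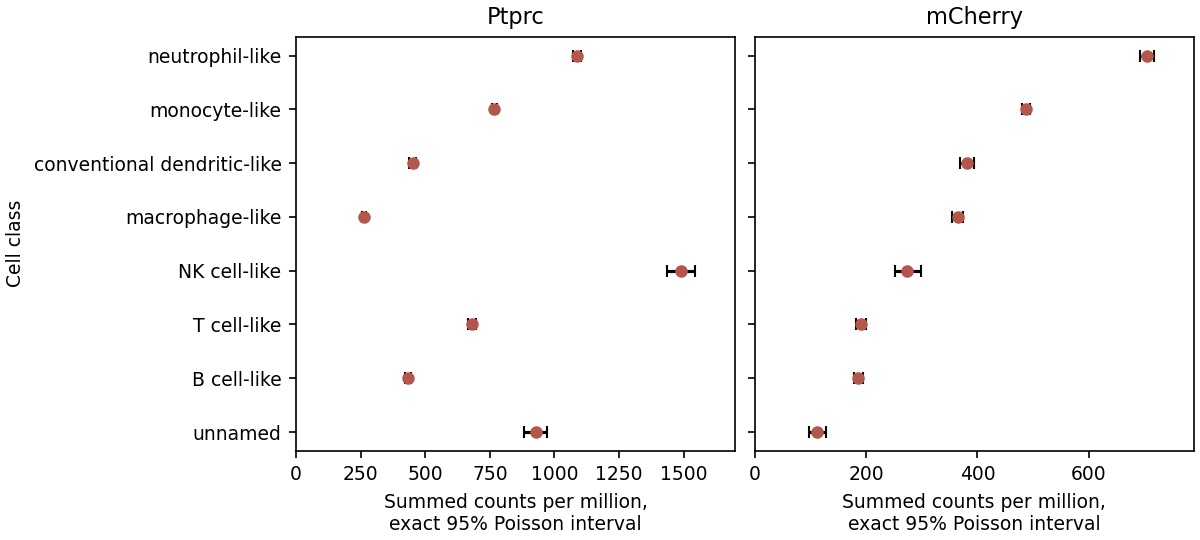
Summed CPM of Ptprc (left) and mCherry (right) in each cell class, with exact 95% Poisson intervals as bars. Ptprc was found in every class, from 263 to 1489.6, and mCherry ran from 111 in unnamed cells to 705 in neutrophil-like cells.

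Fixed gene lists were then compared across the 5 classes of at least 50 cells, to describe which classes of this pool held which lists. The series held no library from unoperated mice, so no level can be tied to pressure overload. Of 110 pairs of 22 lists and 5 classes, 17 had a median log2 ratio to all other cells above the 97.5 percentile of matched random lists and 40 lay below the 2.5 percentile. Genes of these lists, except the haemoglobin and cardiomyocyte genes, were kept out of the clustering, but they vary with genes that were used in it, so a list's level in a class is a description and not independent evidence. Each ratio sets a class against all other cells together and does not rank the classes. Another of the 5 classes held more of C5ar1, Cd36, Cox4i1, H2-D1, H2-K1, Isg15, Ldha, Lgals3 and Ly6e than the class given below. The same held for Notch2, Pkm, Rbpj, S100a4, Skil, Tgfbi, Tubb5 and Vim. Sums over a class weigh deeply sequenced cells more. With each cell weighted alike, 20 of 76 ratios of named genes moved by over 1.5 times, those of Spp1 and Tnnt2 toward 1 and the other 18 away from it. Besides those given with their lists, these were the ratios of Ccl9, Fabp5, Fcgr2b, Fn1 (in both of its lists), H2-Ab1, H2-Eb1, Hbegf, Hes1, Lpl, S100a4, Timp1 and Vim, whose log2 ratios then lay between 1.49 and 3.32. Besides the genes for which this is given below, a single cell held 20.9% to 26.4% of the class counts of Cbr2, Folr2, Hbegf, Lgals3, Timp1 and Tubb5.

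Inflammatory cytokine genes were concentrated in neutrophil-like cells. The NF-kappaB and inflammatory cytokine list summed to 35462 CPM there (35377 to 35547), 3.41 times the level of macrophage-like cells. Cxcl2, a neutrophil chemoattractant, stood at 15548 CPM, 18.5 times the level in all other cells (18.3 to 18.7). Il1b, the interleukin-1 beta gene, stood at 11711 and 8.18 times (8.13 to 8.24), the chemokine gene Ccl3 at 1459.7 and 9.41 times (9.22 to 9.61), and Nfkbia, which encodes the inhibitor of NF-kappaB, at 3899 and 3.02 times (2.99 to 3.05). Of 16 measured members, 12 were higher in neutrophil-like cells, with a median log2 ratio of 1.85 at percentile 100. None of the 16 was higher in monocyte-like cells (median -1.85) or in B cell-like cells (median -4.39). For both classes the other cells include the neutrophil-like cells, so these ratios do not show that a class lacked the genes. The list summed to 10411 CPM in macrophage-like, 4892 in monocyte-like, 2372 in T cell-like and 762 in B cell-like cells. Il1b stood at 1856 CPM in monocyte-like and 1464 in macrophage-like cells. With each cell weighted alike, the log2 ratio of Cxcl2 was 4.96 in place of 4.21.

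Within the 5 classes, neutrophil-like cells also led the leukocyte adhesion list at 3487 CPM (3461 to 3514), 1.47 times the monocyte-like level. The 29 unnamed cells, outside this comparison, held 4184.5 CPM. Of the list's 16 members, 9 were higher in neutrophil-like cells, with a median log2 ratio of 0.51 at percentile 99.8. Selplg, the ligand of P-selectin, was 4.98 times as high as in other cells (4.88 to 5.08) and Icam1, an integrin ligand, 4.78 times (4.63 to 4.93), with 1116 CPM in a cluster of 100 of these cells and 98.4 in the other 173, against 93.6 in other cells, while Cd44 was 1.77 times and the integrin gene Itgb2 1.70 times as high. Immediate early genes, which also respond to tissue dissociation, were highest in neutrophil-like cells at 14893 CPM, 1.27 times the macrophage-like level. Dusp1, a phosphatase of MAP kinases, was 5.09 times as high (5.02 to 5.15), Btg2 2.68, Junb 2.30 and Zfp36 1.90 times. The list's median log2 ratio was 0.67 in neutrophil-like cells (percentile 99.3, 11 of 16 members higher) and 0.59 in macrophage-like cells (percentile 99.9, 10 of 16). Cxcr4, a receptor that retains neutrophils in the bone marrow, made up 85.4% of the angiogenesis and tip cell list, which was highest in neutrophil-like cells at 609 CPM. Cxcr4 was 3.06 times (2.98 to 3.14) and Vegfa, a vascular growth factor, 1.91 times (1.78 to 2.04) the level of other cells, yet 4 of the list's 12 members were higher and its percentile was 46.0.

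Genes of cardiomyocytes were read in neutrophil-like cells as well. The cardiomyocyte RNA list summed to 209.6 CPM there (203 to 216), 5.96 times the macrophage-like level, with 11 of 11 members higher than in other cells and a median log2 ratio of 2.35 at percentile 100. The sum came largely from a part of these cells: 28 cells held 59.5% of the counts, the median was 3 counts per cell, as in monocyte-like cells, and in A965-named cells the list stood at 29.0 CPM, against 28.8 in A965-named monocyte-like cells. Tnnt2, cardiac troponin T, stood at 55.0 CPM, 11.01 times the level of other cells (9.81 to 12.4), or a log2 ratio of 2.79 in place of 3.46 with each cell weighted alike. Of the list's 11 genes, 7 were also cardiomyocyte markers and could enter the clustering. In the 69 neutrophil-like cells richest in these genes the median mitochondrial share was 5.07%, against 0.872% in the 69 poorest, and this share also differed by tag name, from 0.433% in A953 to 4.07% in A951.

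The tissue resident and the recruited, lipid handling macrophage lists were both high in macrophage-like cells as sums over the class. Whether the same cells carried both was not examined. Selenop was above 0 in 49, Cbr2 in 25, Folr2 in 20 and Ccl8 in 8 of the 51 cells. Apoe, Ctsb and Lgals3 were above 0 in all 51 and Spp1 in 40. The resident list summed to 1642 CPM (1621 to 1664), 5.88 times the monocyte-like level, with 9 of 10 members higher and a median log2 ratio of 3.18 at percentile 100. Selenop, a secreted selenoprotein, was 8.25 times as high as in other cells (8.06 to 8.45), Cbr2 132 times (109 to 161) and the folate receptor gene Folr2 109.9 times (87.5 to 139.9). Ccl8 reached 562 times (327 to 1058), but a single cell held 46.6% of its counts and the log2 ratio was 8.25 without that cell and 9.13 with it. The recruited list summed to 23119.5 CPM (23039.5 to 23199.7), 1.88 times the monocyte-like level, with 12 of 13 members higher (median 1.90, percentile 100). Apoe, the carrier of lipids apolipoprotein E, was 4.56 times as high (4.53 to 4.59), the protease gene Ctsb 3.37 times, Spp1, which encodes osteopontin, 21.2 times (20.7 to 21.6) and Lgals3, galectin-3, 1.78 times. Each cell weighted alike gave log2 ratios of 2.80 for Apoe (2.19 by sums), 3.80 for Spp1 (4.41 by sums) and 1.43 for Lgals3 (0.83 by sums).

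Chemokine, phagocytosis and ligand genes were also highest in macrophage-like cells among the 5 classes. Chemokines and their receptors summed to 10094 CPM in macrophage-like cells, 2.02 times the neutrophil-like level, with 11 of 16 members higher (median 1.57, percentile 100). Among these attractants of monocytes and other leukocytes, Ccl6 was 2.13 times, Ccl9 3.65 times (3.596 to 3.70), Ccl7 74.9 times (71.3 to 78.7) and Ccl12 475 times (419 to 541) as high as in other cells. A single cell held 39.97% of the Ccl7 counts, without which the log2 ratio was 5.56 in place of 6.23, and 31.2% of the Ccl12 counts came from a single cell. The phagocytosis and complement list was high in macrophage-like cells at 4006 CPM (median 1.80, percentile 100, 12 of 13 members) and in monocyte-like cells at 2572 (median 0.81, percentile 100, 8 of 13). In macrophage-like cells the Fc receptor genes Fcgr3 and Fcgr2b were 1.91 and 3.59 times as high as in other cells. Cfp, which encodes properdin, was 3.51 times and the C5a receptor gene C5ar1 1.42 times as high. C5ar1 stood at 374 CPM in macrophage-like cells but at 803 in neutrophil-like cells. Growth factors and secreted ligands summed to 287 CPM, 1.35 times the neutrophil-like level, with 8 of 15 members higher (median 0.29, percentile 98.8). Gdf15, a stress-responsive cytokine, was 15.4 times (13.9 to 17.0) and Hbegf, an EGF family ligand, 6.02 times as high (5.43 to 6.69). They were above 0 in 16 and 12 of the 51 cells, and a single cell held 34.6% of the Gdf15 counts, without which its log2 ratio was 3.37 in place of 3.94.

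The summed levels of 3 metabolic lists were highest in macrophage-like cells among the 5 classes. Fatty acid handling genes reached 1088 CPM there, 1.26 times the monocyte-like level, with 8 of 12 members higher (median 0.42, percentile 99.1). Lpl, lipoprotein lipase, was 5.70 times as high as in other cells (5.44 to 5.97), Hadha, an enzyme of beta oxidation, 2.23 times, the fatty acid binding protein gene Fabp5 1.91 times and the scavenger receptor gene Cd36 1.41 times. Oxidative phosphorylation genes summed to 5783 CPM in macrophage-like cells, 1.07 times the monocyte-like level, with 14 of 15 members higher (median 0.54, percentile 99.7), and none of the 15 was higher in neutrophil-like cells. Cox6c was 1.65 times, Ndufa4 1.58 times, Cox7a2 1.45 times and Cox4i1 1.18 times the level of other cells. The class with the highest sum of this list changed under 3 alternative settings. Glycolysis and hypoxia genes summed to 4156 CPM, 1.18 times the monocyte-like level, at percentile 93.9 (median 0.23), against 95.1 (median 0.25) in monocyte-like and 95.8 (median 0.17) in neutrophil-like cells. Gapdh was 1.80 times, Eno1 1.52 times, Ldha 1.30 times and Pkm 1.25 times as high, and the values of Gapdh (95.2%), Eno1 (95.3%) and Pkm (78.1%) were mostly not whole numbers. The same held for Fabp5 (76.5%) and, in lists given below, for S100a4 (84.5%) and H2-D1 (71.1%).

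Of the 5 classes, monocyte-like cells held the highest sums of 5 lists. The 29 unnamed cells, outside this comparison, held more of the TGF-beta (2650 CPM) and Notch (1276 CPM) lists. The 27 NK cell-like cells, also outside it, held more of the Notch list (512 CPM). They also held more B2m (7611 CPM), H2-D1 (3435.5 CPM) and H2-K1 (2804 CPM) but less Psmb8 (259 CPM). The interferon response list reached 7099 CPM (7070.4 to 7128), 2.10 times the macrophage-like level, with 11 of 17 members higher but a percentile of 88.0. Ifitm3, an antiviral membrane protein, was 3.67 times (3.64 to 3.70), Ly6e 1.70 times and the interferon regulator Irf7 1.58 times as high as in other cells. Isg15, a ubiquitin-like protein, was 1.09 times as high, with 23.7% of its counts in a single cell, and its log2 ratio of 0.12 became -0.25 without that cell and -0.41 with each cell weighted alike. MHC class I genes summed to 11268 CPM, 1.11 times the T cell-like level, at percentile 51.6, and T cell-like cells led under 1 setting. B2m, the light chain of class I molecules, was 1.54 times, the immunoproteasome gene Psmb8 1.28 times, H2-D1 1.20 times and H2-K1 1.02 times as high (1.00 to 1.03), and the direction for H2-K1 turned under 2 alternative settings. TGF-beta pathway genes summed to 1571 CPM, 1.097 times the macrophage-like level, with 7 of 17 members higher (percentile 34.8), and macrophage-like cells led under 2 settings. Tgfbi was 2.48 times, the ligand gene Tgfb1 2.32 times, its receptor gene Tgfbr1 1.65 times and the repressor gene Skil 0.849 times the level of other cells, where weighting each cell alike gave Skil a log2 ratio of 0.04 in place of -0.24. Notch pathway genes summed to 479 CPM, 1.00 times the macrophage-like level, at percentile 47.3, and their leading class changed under 3 settings. Hes1, a target of Notch, was 2.34 times (2.26 to 2.42), Lfng 1.40 times, Notch2 1.16 times and Rbpj 0.671 times the level of other cells. Several of these ratios came from 1 of the 2 monocyte-like clusters, which were compared after the data were seen. Tgfbr1 stood at 168 CPM and Hes1 at 503 in the cluster of 82, whose name rested on a tie-break. They stood at 25.1 and 88.1 in the cluster of 99, against 39.8 and 87.9 in all other cells. Lfng, Notch2, Skil, H2-D1 and H2-K1 were also above other cells in the cluster of 82 alone, and Tgfbi and Isg15 in the cluster of 99 alone.

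Matrix and mesenchymal lists rested on few genes in these leukocytes. Of the 5 classes, monocyte-like cells held the most of the activated fibroblast list at 1579 CPM. The 29 unnamed cells, outside this comparison, held 3669 CPM. Thbs1, the matrix glycoprotein thrombospondin-1, made up 86.2% of the monocyte-like sum at 3.48 times the level of other cells (3.42 to 3.53). It stood at 1842 CPM in the cluster of 99 and 149 in that of 82, against 392 in other cells. Runx1 was 0.953 times as high, 3 of 11 members were higher and the percentile was 74.3. Collagens and matrix summed to 868 CPM in macrophage-like cells, 1.59 times the monocyte-like level, and Fn1, fibronectin, made up 78.1% of it. Fn1 was 3.74 times (3.65 to 3.84), the metalloprotease gene Mmp14 9.68 times (8.70 to 10.8) and its inhibitor family member Timp1 2.46 times as high as in other cells, yet 6 of 23 members were higher and the percentile was 51.7. In neutrophil-like cells 14 of the 23 were higher, with a median log2 ratio of 0.17 at percentile 99.8 and a mean of -0.04, from a sum of 65.6 CPM. Of 8 fibroblast markers 6 were highest there too (Col1a1, Col1a2, Col3a1, Dcn, Lum and Gsn, but not Pdgfra or Dpt), as was the cardiomyocyte list: Col3a1 stood at 12.6 CPM and Dcn at 7.33, against at most 4.41 and 3.78 in the other 4 classes of this comparison, with 24.7 and 14.8 CPM in A951-named cells and at most 3.72 and 1.60 in those of the other names. The endothelial to mesenchymal transition list summed to 3517 CPM in macrophage-like cells, 1.05 times the monocyte-like level, with 4 of 7 members higher (median 0.70, percentile 99.2, mean -0.17). The 29 unnamed cells held 3672 CPM of this list. Its leading genes are also genes of myeloid cells: the cytoskeletal gene Vim was 1.77 times, S100a4 1.63 times and the transcription factor gene Zeb2 1.75 times as high. Zeb2 had a log2 ratio of 1.96 to 1.99 in place of 0.80 in 2 settings in which no cells stayed unnamed.

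Among the 5 classes, MHC class II genes were highest in B cell-like and cell cycle genes in T cell-like cells, while the 33 conventional dendritic-like cells, outside this comparison, held more of both (76154 and 561 CPM). MHC class II genes summed to 41237 CPM in B cell-like cells (41119 to 41355), 1.86 times the macrophage-like level, with 7 of 8 members higher (median 1.45, percentile 100). Cd74, the invariant chain, was 3.86 times as high as in other cells (3.84 to 3.87), and the class II chains H2-Aa, H2-Eb1 and H2-Ab1 were 3.18, 2.48 and 2.48 times as high. Weighting each cell alike gave log2 ratios of 2.92 for Cd74 and 2.79 for H2-Aa, in place of 1.95 and 1.67. None of the 8 members was higher in neutrophil-like cells, with a median of -5.37. Cell cycle genes summed to 522 CPM in T cell-like cells (509 to 536), 1.17 times the macrophage-like level, with 10 of 11 members higher (median 0.80, percentile 98.3) and none of the 11 higher in neutrophil-like cells. These 11 leave out Mki67, Top2a, Cdk1, Birc5 and Ccnb1, which are markers of dividing cells. Of these, Mki67 was highest in the neutrophil-like cluster of 100 cells, at 64.7 CPM against 11.8 over all cells. Top2a, Cdk1 and Birc5 were highest in the conventional dendritic-like cluster and Ccnb1 in the NK cell-like cluster. Pcna, the replication clamp, was 1.34 times (1.28 to 1.40) and Tubb5, a tubulin, 1.62 times as high (1.55 to 1.70), with 74.1% of the Pcna values not whole. Haemoglobin genes, not set against random lists, reached at most 21.4 CPM, in B cell-like cells.

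**Figure D4:**
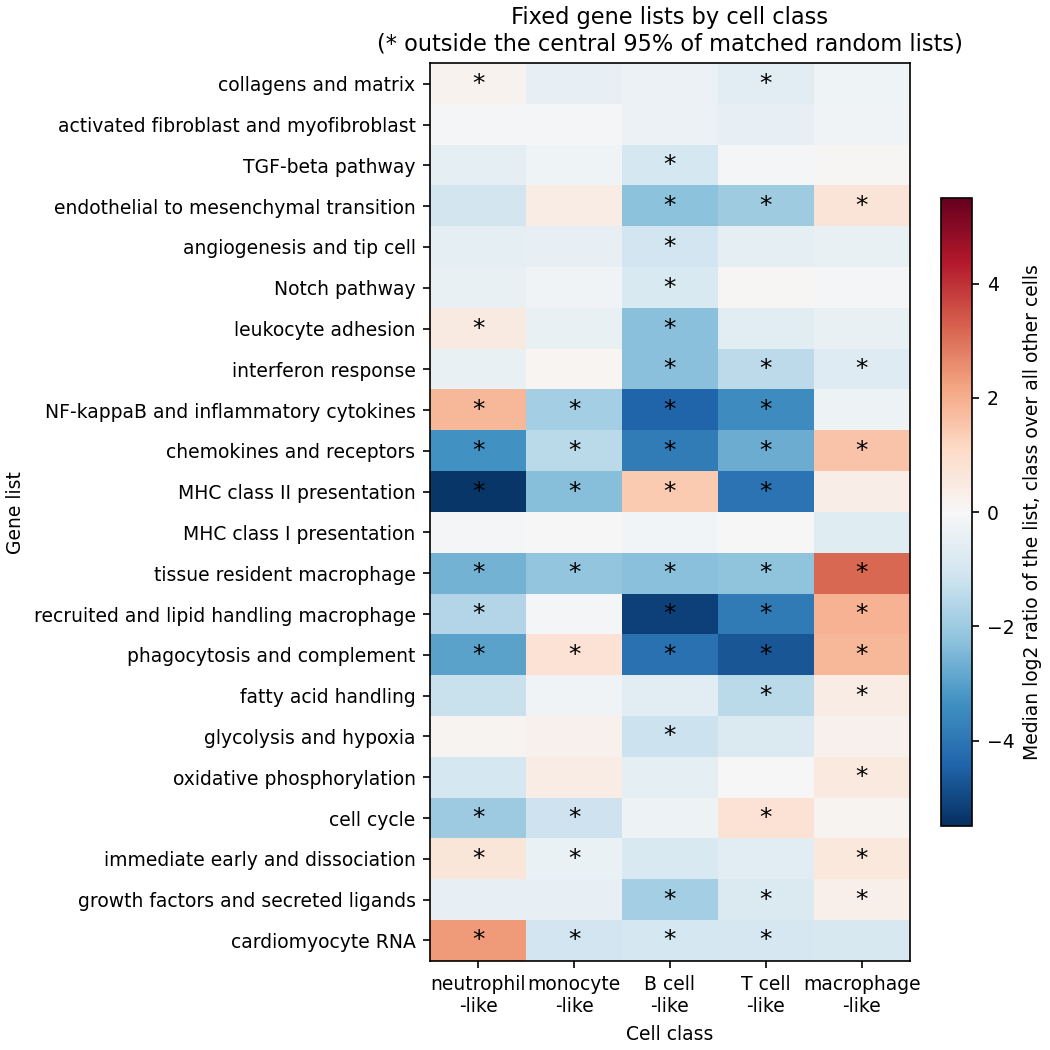
Median log2 ratio of each fixed gene list (vertical axis) in each class of at least 50 cells over all other cells (horizontal axis), coloured from blue (lower) to red (higher), with a star where the median lay outside the central 95% of matched random lists. Red starred fields include the NF-kappaB list (1.85) and cardiomyocyte RNA (2.35) in neutrophil-like cells, and the resident macrophage list (3.18) in macrophage-like cells.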

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

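All tests in this part were chosen after the result was seen, except the test of a few cells as the source of the cardiomyocyte genes, which was set before. The hashtag library held barcodes that the transcriptome comparisons did not use: 5465 barcodes with at least 2000 tag counts lay outside the matrix, against 174 of the 878 cells in it. At 500 tag counts or more the numbers were 12238 and 247.

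No endothelial, endocardial, lymphatic, mural, glial or epicardial cell was found in the matrix by its markers, and fibroblast and cardiomyocyte markers in only 4 and 11 cells, although CD45-negative fractions were pooled. Removal of the absent types by the mitochondrial limit was argued against for cells that meet the marker rule. Among all 878 cells, before that limit, the upper bound on the share of such cells was 0.419% for each of the 7 types. Fibroblasts and cardiomyocytes were not among these 7 types. Of the cells with their markers, 2 of 4 and 7 of 11 were over the limit. It stays open whether barcodes of the 7 absent types were left outside the matrix. The 5465 strongly tagged barcodes leave room for them, but the RNA of those barcodes was not analysed here. Losses in dissociation, sorting or capture were not tested, and no biological explanation was tested.

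Most cells named A953 or A965 had more counts of A951 than of the tag in their name. Names set from each tag's counts divided by that tag's sum over the cells of the matrix are a candidate explanation: this scaling gave the deposited name in 826 of 826 singly named cells, against 630 with medians over the cells of the matrix, 523 with sums over all barcodes, 490 with no scaling and 519 with sums over 67162 background barcodes of 20 to 99 tag counts. Under such a scaling the sums matter, and 5 cells held 77.4% of the A953 counts and 45.2% of the A965 counts of the matrix. Free A951 tag at a common level stays open. A comparison by name cannot decide it, because under such a scaling the names depend on the A951 counts themselves. In monocyte-like cells the median A951 count was 68.5 (quartiles 51.5 to 87.8) in A965-named cells and 11.5 (quartiles 7.5 to 14.5) in A952-named cells. In neutrophil-like cells the values overlapped, with 31.5 (quartiles 14.5 to 49.8) against 10.0 (quartiles 7 to 16). Which tag these cells truly carried was not settled, and no biological explanation was tested.

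As a list, cardiomyocyte genes were higher in neutrophil-like cells than in every other class, with 282 CPM in those named A951, 71.9 in A952, 59.5 in A953 and 437 in doublets, but 29.0 in A965, against 28.8 in A965-named monocyte-like cells, and 291 CPM in 5 B cell-like cells named doublet. Free RNA spread evenly over the pool was argued against for the sum, with a mean of 14.5 counts of the list per neutrophil-like cell, 7.12 times that of B cell-like cells, though 1.52 times that of the more deeply sequenced macrophage-like cells (9.55), and it stays open for neutrophil-like cells at or below their median of 3 counts (quartiles 1 to 11), against medians of 3 in monocyte-like, 5 in macrophage-like and 1 in B cell-like cells. The 28 richest cells, which held 59.5% of the counts, were argued against as the only source. Without them the level was still 5.73 times that of B cell-like cells treated alike (95.7 against 16.7 CPM). The test could not argue against a larger part of these cells as the source. The list's median was 589 CPM in the 69 richest neutrophil-like cells and 0 in the 69 poorest. Pieces of cardiomyocytes in the same wells stay open: the 69 cells richest in the list had 5.82 times the median mitochondrial share of the 69 poorest, but that share also differed by name (4.07% in A951, 0.872% in A952, 0.433% in A953, 0.759% in A965 and 3.51% in doublets), and within A951-named cells the ratio was 2.35 with a bootstrap interval of 0.965 to 6.55, within A952 2.13 (1.16 to 4.56), within doublets 1.97 (0.451 to 9.23), and within A953 and A965, with 5 and 7 cells a side, 0.637 and 0.591. Uptake of such material and damaged cells that gather free RNA were not tested apart from this, and no biological explanation was tested.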

How the results depend on the processing

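Tests chosen after the data were seen are the tag share of 0.6, cells named doublet left out, ties left unnamed and genes without their highest cell, as well as every alternative for named genes and clusters and scrublet removal for pairs of lists and classes. Shares of the 8 classes stayed within their intervals at resolution 2 and without cells named doublet. A limit of 1000 counts could not move them, since every cell had at least 28406.6 counts. The macrophage-like share moved to 8.34% with at most 10% mitochondrial counts, 8.87% at resolution 0.5, 10.04% with 15 components, 9.57% with all variable genes and 9.24% without scrublet doublets, and in these 5 settings the unnamed share was 0. With ties left unnamed, the monocyte-like share was 11.6% and the unnamed share 12.95%. Tags called by the highest count gave A951 74.7%, A952 19.5%, A953 1.48%, A965 3.19% and no call in 1.14% at a share of 0.5, A951 72.8%, A952 18.5%, A953 1.37% and A965 2.85% at 0.6, A951 55.7%, A953 1.14%, A965 1.48% and no call in 26.9% at 0.8, and A951 54.4%, A953 1.37%, A965 2.85% and no call in 23.6% with at least 50 counts. The tag scaling that gives the deposited names differs from such calls by construction. The class with the highest sum stayed for 20 of 22 lists without technical genes and for 20 to 23 of 23 lists in the other 5 settings. The log2 ratio to the next class turned to -0.202 for MHC class I and -0.0800 for oxidative phosphorylation without technical genes, to -0.0228 for TGF-beta, -0.267 for Notch and -0.0296 for oxidative phosphorylation without scrublet doublets, to -0.0637, -0.338 and -0.0296 for these at resolution 0.5, and to -0.0757 for Notch without cells named doublet. Among named genes, with each cell weighted alike, Skil turned to 0.0401 and Isg15 to -0.405; Isg15 was -0.253 without its highest cell, and H2-K1 was -0.00227 at resolution 0.5 and -0.0265 without cells named doublet. The cause was not tested, except that for Isg15 a single cell decided the direction of the sum. Without a change of direction, 317 other values of named genes and 106 of list ratios left their counting intervals, while 210 and 22 stayed within them. Pairs above the random lists numbered 16 to 19 in 3 settings (17 in the report) and pairs below 39 (40 in the report). Comparisons by sorted fraction and their alternatives were not run and have no value, since no tag is tied to a fraction. No paired analysis was possible because there is 1 library of each kind. At this number of cells, cells with 3 markers of a type could still make up 0.419% with none seen. Cells of the type that miss this marker rule would come on top. Classes under 50 cells were left out of the report's comparison of lists.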

Other observations

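All comparisons in this part, and the genes named in them, were chosen after the data were seen. Neutrophil-like cells fell into a cluster of 173 cells led by granule and calgranulin genes (Retnlg, Camp, S100a8, S100a9) and a cluster of 100 cells led by Il23a, Gpr84, Icam1 and Csf1. In the smaller cluster 13 of 14 measured genes of the NF-kappaB list were higher (median log2 ratio 0.96, percentile 100) and 7 passed the rule for genes. Il1a was 5.83 times as high (5.31 to 6.42), Tnfaip3, a brake on NF-kappaB signalling, 3.42 times (3.24 to 3.61), Tnf 2.60 times, Nfkbia 2.57 times and Ccl3 2.16 times. Icam1, among the genes that lead the cluster, was 11.3 times as high (10.7 to 12.1) and Csf1 5.44 times (4.99 to 5.95). Cardiomyocyte genes were higher there for 8 of 10 (median 0.33, percentile 47.2), and 2 passed the rule. Ccl2 was 6.62 times as high (5.97 to 7.35), with 39.6% of its counts in a single cell, and its log2 ratio of 2.73 was 1.85 without cells named doublet. Ccl6 was lower at 0.277 times, Vim at 0.271 times and Rtp4, an interferon response gene, at 0.476 times, and the interferon list had a median log2 ratio of -0.32 (percentile 0.96), but 8 of its 17 genes were higher, among them the most abundant, Ly6e at 1.87 times and Ifitm3 at 1.21 times.

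Monocyte-like cells fell into a cluster of 99 cells with Ly6c2, Chil3 and Vcan, the markers of classical monocytes, and a cluster of 82 cells with Ace, Treml4 and Nr4a1, whose median counts per cell were 227114 and 106481. In the cluster of 82, 8 of 9 MHC class I genes were higher (median log2 ratio 1.11, percentile 99.9), with H2-K1 at 3.38 times (3.31 to 3.45) and B2m at 2.43 times. Notch pathway genes had a median of 1.40 (percentile 99.9, 7 of 9 higher), with Hes1 at 5.71 times (5.42 to 6.01) and Nrarp, a Notch target, at 21.8 times (17.1 to 28.3), and TGF-beta pathway genes a median of 1.09 (percentile 99.9, 11 of 14 higher), with Tgfbr1 at 6.68 times (6.07 to 7.35) but Tgfbi at 0.319 times. Of the TGF-beta genes 5 passed the rule as higher and 1, Tgfbi, as lower. Immediate early genes, which also respond to dissociation, were higher in the cluster of 82 too (median 0.76, percentile 99.9, 13 of 16 higher). So were cardiomyocyte genes (median 1.01, percentile 97.8, 5 of 6 higher). Cd36 was 38.0 times (34.9 to 41.5), Pparg, a nuclear receptor of lipid metabolism, 61.9 times (49.6 to 78.3) and Itgal, an integrin of leukocyte adhesion, 4.31 times as high. MHC class II genes were lower, with a median of -1.80 (percentile 0.02) and 6 of 8 genes passing the rule, and chemokine genes had a median of -1.66 (percentile 0, 8 of 11 lower). Fn1 stood at 0.0141 times, Thbs1 at 0.0807 times and the scavenger receptor gene Msr1 at 0.105 times the level of the cluster of 99. Ccr1 stood at 0.0120 times, a log2 ratio of -6.39 that was -8.15 without the highest cell of each cluster. Over both pairs of clusters 97 results of genes in lists passed the rule, and none changed direction under 3 alternatives. The clusters were formed on the same cells, so these differences are not independent evidence.

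The groups below have fewer than 50 cells each and were left out of the report's comparison of lists, so their percentiles rest on few cells. Conventional dendritic-like cells held the highest MHC class II level of any class at 76154 CPM, with 8 of 8 genes higher than in other cells (median 2.88, percentile 100). In these cells 14 of 17 interferon response genes (median 0.62, percentile 100) and 10 of 11 cell cycle genes (median 1.43, percentile 100) were higher as well. NK cell-like cells held 23329.9 CPM of the chemokine list, 98.8% of it from Ccl5, a chemokine gene of cytotoxic lymphocytes. Unnamed cells held 3669 CPM of the activated fibroblast list, 55.7% of it from Runx1, a transcription factor gene of blood cells.

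Classes by tag name are given as values. Neutrophil-like cells made up 42.1% of kept A951 cells, 45.5% of A952, 16.7% of A953, 11.3% of A965 and 69.6% of cells named doublet. B cell-like cells made up 15.5%, 2.99%, 28.9%, 27.9% and 10.9% of the same groups, T cell-like cells 7.59%, 0.746%, 25.4%, 19.0% and 4.35%, and macrophage-like cells 5.06%, 16.4%, 1.75%, 3.64% and 4.35%. The median number of tag counts was 1759 in neutrophil-like cells, 216 in macrophage-like, 109 in monocyte-like, 56 in B cell-like and 45 in T cell-like cells. In cells named doublet the highest tag held a median of 98.4% of the tag counts and a share of at least 0.8 in 39 of 52 cells. It was A952 in 31 of 52 cells, A965 in 12, A951 in 8 and A953 in 1, and how these names were given was not recovered. The other 7 tags of the hashtag table had at most 91 counts each over all barcodes.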
